A study of Arabidopsis thaliana with 9 samples.

How the data were processed

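Total RNA from whole Arabidopsis thaliana plants at growth stage 1.04 had been labelled with biotin and hybridised to Affymetrix ATH1 arrays, 1 sample per array. The deposited values are signals in intensity units on a linear scale, made with MAS5 in GCOS per the submitters' processing notes, whose versions are not given in the sources used here. The deposited signals had a 2% trimmed mean of 100 on every array, so the authors' global scaling was kept and no further normalization was applied. Detection calls were not used here. Samples were grouped by the line in their labels into control C2S1, line 348 and line 409, with 3 arrays each. The titles number the arrays of line 348 as 1, 1 and 3, and replicate numbers in the text follow the order of the samples. No batch is given in the labels.

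Affymetrix control probe sets, 64 of them, were left out. Gene names came from the given table of probe genes and from the given RefSeq gene table, joined by gene identifier. Of the other 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 had none named, and 77 of those with 1 gene had no match in the RefSeq table. Signals were put on the log2 scale after adding 4.95, the median over arrays of the 20th percentile. A probe set was tested if its signal was above the array's 40th percentile on at least 3 of the 9 arrays, which kept 14199, of which 7633 had 1 gene, covering 7575 genes, and 6279 had none named.

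Changes were tested in R 4.3.3 with limma 3.58.1, in 1 linear model of the 9 arrays with moderated variances and an intensity trend, with 6 residual degrees of freedom and a median of 8.86 prior degrees of freedom. The Benjamini-Hochberg adjustment ran over all tested probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. The median SE of a log2 change was 0.159. Gene lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and contrasts. A list of low-oxygen genes, added later, was adjusted over its own contrasts alone. The statmod 1.5.0 package was used for the fit with a block.

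Genes were named by a rule fixed before the values were read, for probe sets assigned to exactly 1 gene. It took up to 8 called genes per direction with the largest change of at least 2-fold and no overlap between groups, or 4 for line 409 against line 348. It added up to 4 called members of each fixed list, the genes DDM1, MET1, CMT3, SAHH1 and ROS1, and the top 5 called in both lines. List members that passed over the list alone or did not pass, called probe sets without a gene name, genes near the threshold and members of families were named after their values were seen. The 17 fixed lists were written before the files were read. Lists by rule of pericentromeric loci and of plastid-encoded genes were also planned then, the latter by locus name but made from the annotated chromosome. Planned lists of transposable element genes, of pericentromeric loci without them and of mitochondria-encoded genes were not tested. Lists of pseudogenes and symbol families with at least 8 probe sets were added after the gene tables were read and before any test. The pseudogene count per array, the pooled comparison, the covariance of the lines and the low-oxygen list were added after results had been seen.

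The code was checked on simulated data with known changes. With 20 changed probe sets in each of 20 runs, false calls averaged 0.8 per run for line 348 and 0.25 for line 409, and with 200 changed in each of 5 runs, 7 and 7.8. In a first simulated draw, a single list without any shift had a camera adjusted p of 0.0348 for line 348 and 0.0367 for line 409. A larger check was added after that was seen: of 1000 unshifted lists of 30 probe sets, 2.4% had p under 0.05 for line 348 and 2.9% for line 409, with 1 and 0 past the adjusted threshold. A list shifted by 0.4 log2 units in line 409 was found in 20 of 20 data sets, and no shifted list was tried for line 348. All these simulations drew arrays and probe sets independently, so they do not show how camera behaves on correlated lists. In the real data the plastid-encoded list had an estimated correlation of 0.509. Of 100 groupings of the real arrays, 79 had at least 1 list test past the threshold.

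Alternatives tried were quantile normalization, median centring, no pseudocount and a pseudocount of 21.5, no filter and a filter at the 60th percentile. Further ones were only probe sets with 1 gene, no intensity trend, array weights, only the 6 arrays compared, each array left out in turn, fry for the lists, and the replicate number as a block.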

Results

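Gene expression was measured in whole Arabidopsis thaliana plants of 3 lines with Affymetrix ATH1 arrays, which carry short oligonucleotide probes grouped into probe sets. The control line, C2S1, is called wild type in its sample titles, while its genetic variation label reads knock out mutation. Lines 348 and 409 are T-DNA insertion mutants according to the labels, and the series title speaks of epigenetic mutants. The labels name no disrupted gene for either line, so no targeted gene could be examined first. Each line was hybridised on 3 arrays, 9 in all, from plants grown for 17 days at 21 C with 16 h of light and 8 h of dark, sown at 25 seeds per plate. Nothing in the labels says whether the 3 samples of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. The 2% trimmed mean signal was 100 on every array, and replicate arrays of a line correlated at r = 0.963 to 0.985 across the 14199 probe sets tested, which are not independent replicates.

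Line 348 was compared with the control to find transcripts that differ in this mutant. The largest change was a rise of probe set 266680_s_at, from 28.7 ± 14.4 to 146 ± 6.16 signal units (SD, n = 3 arrays each), a log2 change of 2.25 with limma adjusted p = 0.00182. Probe set 253502_at rose from 60.1 ± 1.81 to 196 ± 55.7, a log2 change of 1.59 with limma adjusted p = 0.0245. Probe set 245276_at fell by 0.90 on the log2 scale, from 227 ± 20.4 to 120 ± 18.4, with limma adjusted p = 0.0326. The gene table used here names no gene for any of these 3 probe sets, and they are given because they were the whole list of calls. All 3 showed the direction on each of the 3 mutant arrays, with no overlap with the control values, which chance gives for 10% of probe sets. Calls of 253502_at and 245276_at hung on single arrays or settings: for 253502_at, line 348 against control, the limma adjusted p was 0.207 without the intensity trend and up to 0.201 with 1 array left out, and for 245276_at, line 348 against control, it was 0.207 and up to 0.289.

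WRKY6, a transcription factor of senescence and defence, was the only gene of the fixed lists that rose in line 348 when adjusted over the list alone. Its signal was 27.6 ± 3.65 in the control and 48.5 ± 3.47 in line 348 (SD, n = 3), a log2 change of 0.72 with SE 0.177. The limma adjusted p was 0.0021 over the 2 tested senescence genes and 0.414 over all probe sets tested, so the call held for the list alone. WRKY53, the other tested senescence gene, had a log2 change of -0.20 with SE 0.278. MGL, which encodes methionine gamma-lyase, had a log2 change of -0.39 with limma adjusted p = 0.0508 over its list alone and 0.804 over all probe sets. Beyond WRKY6, no tested member of the fixed lists passed in line 348 when adjusted over its list alone, and over all probe sets no member passed.

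In all, limma called 3 probe sets in line 348, 2 higher and 1 lower, at an adjusted p under 0.05, and 801 had an unadjusted p under 0.05 where chance gives 710. The 95% confidence interval of the change lay inside a 2-fold range in either direction for 96.9% of probe sets, and its median reach to either side was 0.339 on the log2 scale. The count depended on single arrays: it was 1 without control replicate 1, 1 without control replicate 2, 24 without control replicate 3, 8 without line 348 replicate 2, 1 without line 348 replicate 3 and 5 without line 409 replicate 3. In limma fits it was 0 among the 7633 probe sets with 1 named gene, of which 401 had an unadjusted p under 0.05, 10 with array weights, 6 with only the arrays of the 2 groups and 1 without the intensity trend.

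Line 409 was compared with the control for the same purpose, and here 2 called probe sets carried a gene name. AT5G22850 fell by 1.68 on the log2 scale, from 89.0 ± 3.03 to 24.8 ± 6.71 signal units (SD, n = 3 arrays each), which was 3.21-fold lower with the pseudocount added to each signal, with limma adjusted p = 0.000752. Its values were 86.3, 92.3 and 88.4 in the control and 30.8, 17.5 and 26.1 in line 409. AT5G52070 fell by 1.03 on the log2 scale, from 129 ± 21.1 to 59.9 ± 3.47, 2.04-fold lower by the same measure, with limma adjusted p = 0.00741. AT5G22850 belongs to the aspartyl protease family, and AT5G52070 encodes a protein with an agenet domain, a fold related to readers of histone marks. For AT5G52070, line 409 against control, the limma adjusted p was 0.0689 without control replicate 1, 0.109 without control replicate 2 and 0.0778 without line 409 replicate 2.

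The other 4 called probe sets of line 409 have no gene in the table used here and are given because they complete the list of calls. Probe set 258618_at rose from 21.4 ± 4.96 to 63.4 ± 6.92 signal units (SD, n = 3), a log2 change of 1.38 with limma adjusted p = 0.00588. Its signals on control replicates 1 and 3, 18.5 and 18.7, lay below the 40th percentile of those arrays. The log2 change moved between 0.986 and 1.582 with the pseudocount. Probe set 251861_at rose from 55.0 ± 10.0 to 138 ± 25.7, a log2 change of 1.26 with limma adjusted p = 0.00588. Probe set 245276_at fell by 1.02 on the log2 scale, to 109 ± 5.83, with limma adjusted p = 0.00588, and 253922_at fell by 0.97, from 568 ± 66.7 to 288 ± 43.8, with limma adjusted p = 0.00866. For 253922_at, line 409 against control, the limma adjusted p was 0.0988 without the intensity trend, 0.0689 without control replicate 1, 0.112 without control replicate 2 and 0.0804 without line 409 replicate 2. Without line 409 replicate 2, the other 3 were not called either, each with limma adjusted p = 0.05 after rounding, and for 245276_at, line 409 against control, it was 0.0631 without control replicate 2.

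**Figure D1:**
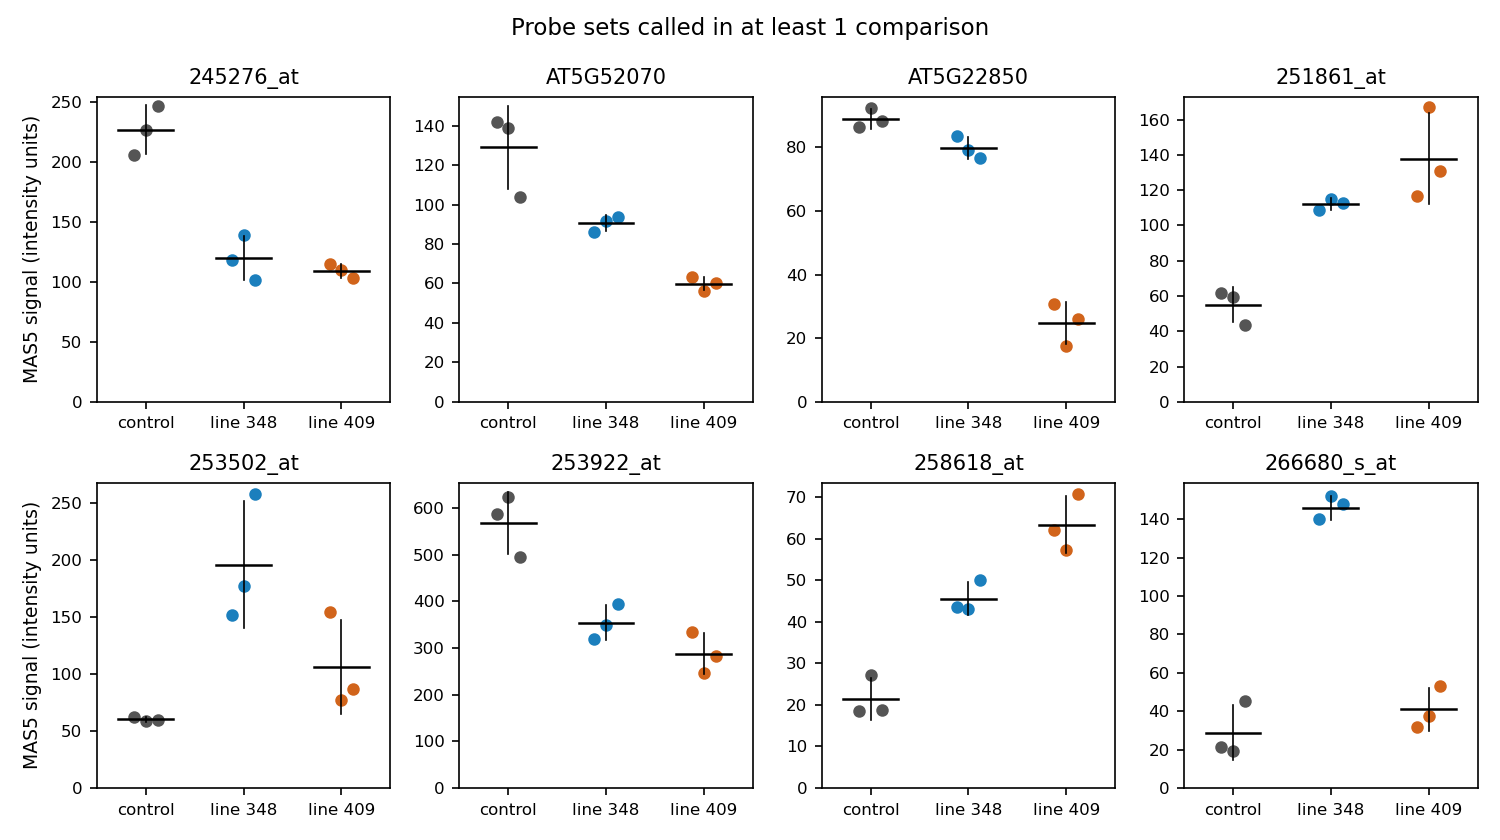
MAS5 signal (intensity units) of the 8 probe sets called in at least 1 comparison, with a point per array, the mean as a horizontal line and the SD as a vertical line for the control, line 348 and line 409 (n = 3 each). AT5G22850 had a mean of 89.0 in the control, 79.9 in line 348 and 24.8 in line 409, and 266680_s_at had means of 28.7, 146 and 40.9.

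Among the fixed lists, 5 tested genes passed in line 409 when adjusted over the list alone, and over all probe sets none of the 5 did. These lists had 1 to 3 tested members, 21 entries were tested in all, and no adjustment ran over the lists. Of all 14199 tested probe sets, 1727 had an unadjusted limma p under 0.05 in line 409, so values of this kind were not rare. The S-adenosylmethionine cycle supplies the methyl group for DNA methylation. Of the 19 genes of its list 3 were tested, and 2 of these fell when adjusted over the list alone. The genes of the list that make S-adenosylmethionine were not among them, so the cycle as a whole was not read. MGL had a log2 change of -0.45, from 87.5 ± 13.6 to 62.0 ± 1.81, with limma adjusted p = 0.0203 over the list alone and 0.245 over all probe sets. CBL, cystathionine beta-lyase of methionine synthesis, had a log2 change of -0.30, from 627 ± 15.5 to 509 ± 58.3, with limma adjusted p = 0.0487 and 0.362. HMT1, a homocysteine methyltransferase, did not pass, with a log2 change of 0.28 and SE 0.197.

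QQS, an orphan gene that affects starch content and whose expression varies with DNA methylation, rose in line 409 from 173 ± 23.9 to 232 ± 29.9 (SD, n = 3), a log2 change of 0.42. Its limma adjusted p was 0.0207 over the 2 tested members of the methylation-controlled list alone and 0.268 over all probe sets, and MPC, the other tested member, had a log2 change of 0.06. UGT78D2, a flavonoid glucosyltransferase, fell by 0.52 on the log2 scale, from 104 ± 3.81 to 71.7 ± 6.18, with limma adjusted p = 0.00292 over the list alone and 0.194 over all. PDF1.2, a plant defensin induced by jasmonate, rose from 17.3 ± 3.89 to 28.1 ± 4.25, a log2 change of 0.58 with limma adjusted p = 0.0422 over the list alone and 0.387 over all. Its control mean was dim, below the 40th percentile of each control array, 20.88 to 21.47. UGT78D2 and PDF1.2 were each the 1 tested member of their lists, so the list-alone value involved no adjustment.

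The remaining tested genes of the fixed lists passed in neither mutant line. The DNA demethylase DME was read by 2 probe sets, with log2 changes of 0.32 and 0.09 in line 348 and 0.04 and 0.17 in line 409. The light-harvesting genes LHCB4.1 and LHCB4.2 had log2 changes of 0.09 and -0.02 in line 348 and 0.09 and -0.03 in line 409, and PSAE1 of photosystem I had a log2 change of 0.26 in line 409 with limma adjusted p = 0.0802 over its list alone. The cytokinin response regulator ARR15 had log2 changes of 0.34 and 0.30 in lines 348 and 409, with SE 0.254, and ARR16 had -0.04 in both. The flowering regulator GI had 0.21 and 0.15, AGL24 had -0.28 and -0.08, and the replication gene MCM7 had -0.20 in both lines. The defence gene SAG101, the cold gene COR47 and the root gene PYK10 had changes of 0.10, -0.04 and -0.03 in line 348 and -0.01, 0.09 and -0.04 in line 409.

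**Figure D2:**
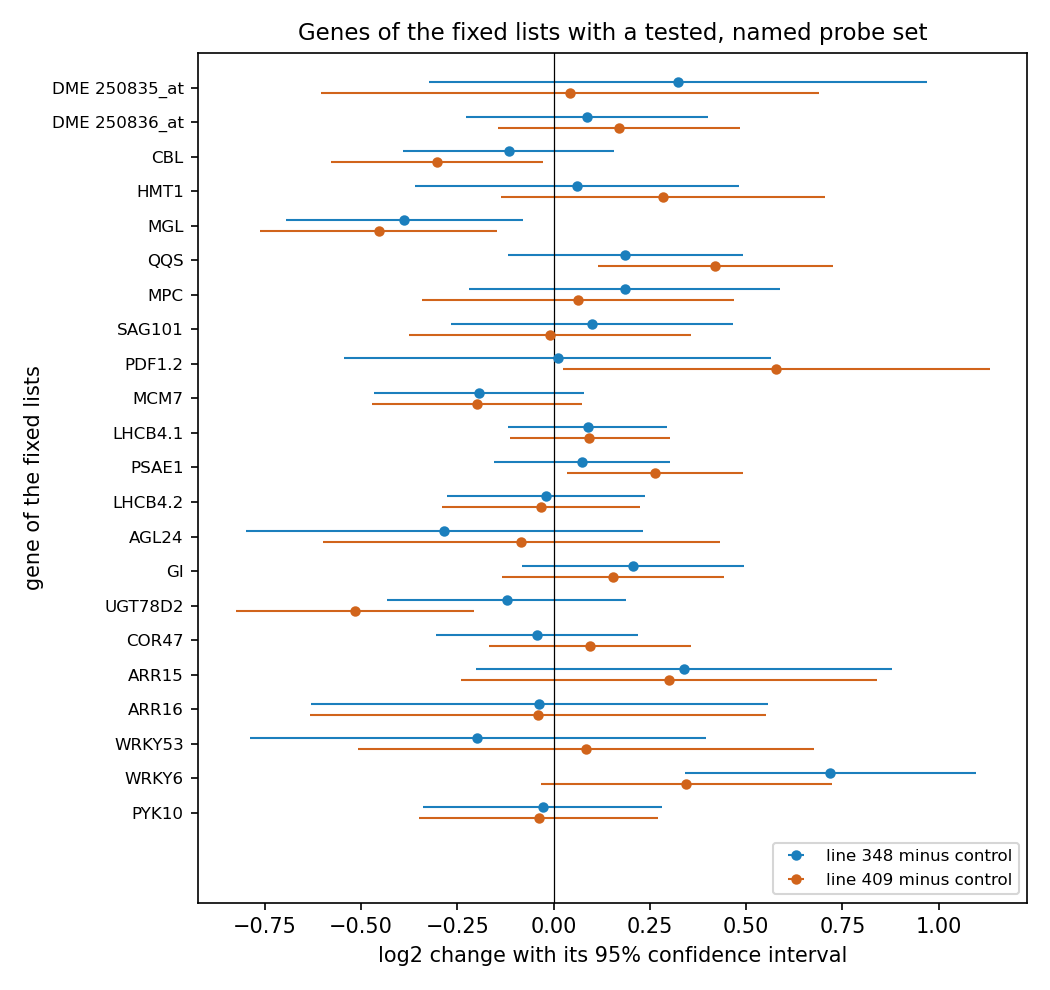
Log2 change of each tested, named probe set of the fixed lists against the control, for line 348 and line 409 (n = 3 arrays per group). Points are the estimates and horizontal bars their 95% confidence intervals, with WRKY6 at 0.72 in line 348 and UGT78D2 at -0.52 in line 409.

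In all, limma called 6 probe sets in line 409, 2 higher and 4 lower, and 1727 had an unadjusted p under 0.05, 764 higher and 963 lower, where chance gives 710. The 95% confidence interval lay inside a 2-fold range in either direction for 95.6% of probe sets. The count was 3 without control replicate 2, 60 without control replicate 3, 12 without line 409 replicate 1, 1 without line 409 replicate 2 and 11 without line 409 replicate 3, and it was 40 with array weights. Spike-in controls lay at a mean of -0.21 log2 units from the average of all arrays in line 409 and 0.12 in the control, with exact permutation p = 0.1, the smallest possible for 3 against 3 arrays.

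Lines 409 and 348 were compared directly, which is also the test of whether their changes from the control differ. AT5G22850 was lower in line 409 than in line 348, at 24.8 ± 6.71 against 79.9 ± 3.49 signal units (SD, n = 3 arrays each), a log2 change of -1.54 with limma adjusted p = 0.00245. Probe set 266680_s_at was lower in line 409, at 40.9 ± 11.1 against 146 ± 6.16, a log2 change of -1.75 with limma adjusted p = 0.02. AT5G52070 had a log2 change of -0.56 between the lines with limma adjusted p = 0.471. UGT78D2 had a log2 change of -0.39 and PDF1.2 of 0.57 between the lines, with limma adjusted p = 0.0162 and 0.0452 over their lists alone, 0.622 and 0.658 over all probe sets. For WRKY6 the change between the lines was -0.37 with limma adjusted p = 0.104 over the list alone.

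In this comparison limma called 2 probe sets, both lower in line 409, while 1062 had an unadjusted p under 0.05. The 95% confidence interval lay inside a 2-fold range in either direction for 96.6% of probe sets. The count was 6 without line 348 replicate 2 and 1 without line 348 replicate 3, line 409 replicate 1 or line 409 replicate 2, each left out in turn. For 266680_s_at, line 409 against line 348, the limma adjusted p was 0.294 with no filter on dim probe sets, 0.125 without the intensity trend and up to 0.243 with 1 array of the 2 lines left out.

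Both lines were then set side by side. Probe set 245276_at was the 1 probe set called in both, lower in each, and 5 of 100 groupings of the 9 arrays, the real one included, shared at least 1. No probe set with a gene name was called in both lines. Some changes near the threshold went the same way in both, which the shared control arrays favour. Probe set 251861_at, called in line 409, had a log2 change of 0.982 in line 348 with limma adjusted p = 0.062. AT4G33380 had log2 changes of -1.824 and -2.044 in lines 348 and 409, with limma adjusted p = 0.226 and 0.0604. AT5G22850, called in line 409, had only -0.148 in line 348. The shared count was 22 without control replicate 3, 2 without line 348 replicate 2 or line 409 replicate 3, and in limma 0 without control replicate 1, control replicate 2, line 348 replicate 1, line 348 replicate 3 or line 409 replicate 2, with 202 to 308 shared at an unadjusted p under 0.05. Across probe sets, the log2 changes of lines 348 and 409 correlated at r = 0.565, against 0.501 for simulated unchanged groups that share the 3 control arrays, and 69.2% of probe sets had the same sign, against 66.7%. The covariance of the changes was 0.0288, against a simulated mean of 0.0195, a difference of 0.00928. Without control replicate 3 the covariance was 0.0459. The reference for that value, 0.0292, was not simulated but calculated from the spread within groups. Both references pool the spread of all 9 arrays, control replicate 3 included, so the size of the excess depends on that choice. The control arrays were not divided between the lines, so the part of this excess that comes from the shared controls was not measured.

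**Figure D3:**
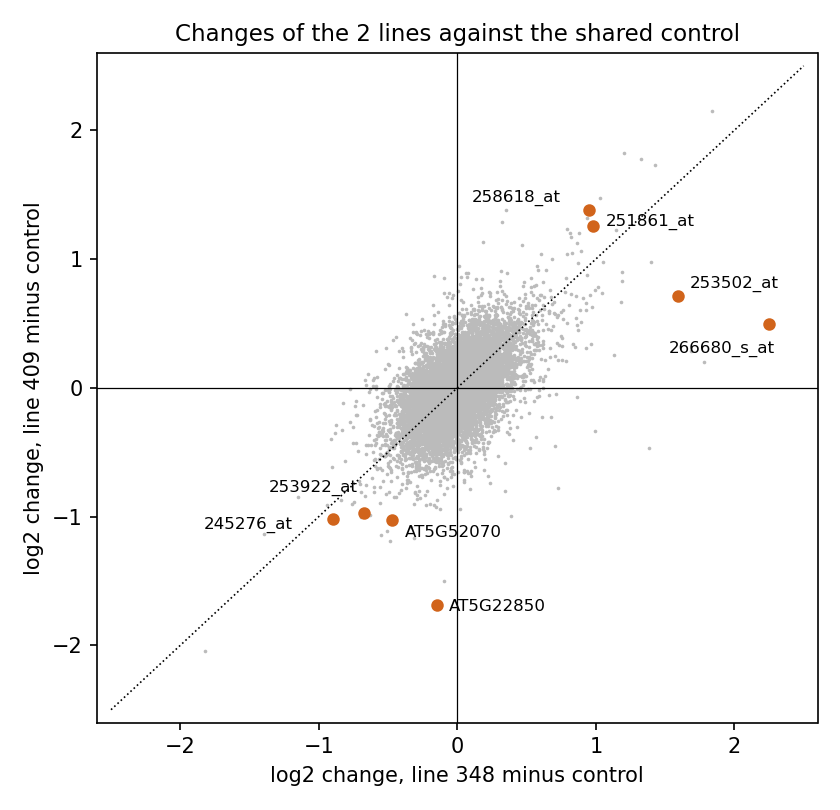
Log2 change of line 409 minus control (vertical axis) against that of line 348 minus control (horizontal axis) for the 14199 tested probe sets, as grey points, with the 8 called probe sets in orange and the dotted line marking equal changes. AT5G22850 lies at -0.15 for line 348 and -1.68 for line 409, while 266680_s_at lies at 2.25 and 0.50.

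Gene groups were tested as whole lists. Genes encoded in the plastid genome were higher in line 348, with 56 of 69 probe sets higher and 13 lower, a median log2 change of 0.09 and camera adjusted p = 0.013. With an estimated correlation the camera p was 0.444 and the adjusted p 0.916, and no single member passed when adjusted over the list alone or over all probe sets. The 3'/5' signal ratio of GAPDH, a sign of RNA quality, was 1.58 to 1.70 on the arrays of line 348 and 1.79 to 1.97 on those of the control, with exact permutation p = 0.1, the smallest possible. The ratios of actin and ubiquitin overlapped between these groups. Actin had 6.39 to 11.35 in line 348 and 8.97 to 11.96 in the control, with exact permutation p = 0.3. Ubiquitin had 1.47 to 1.70 and 1.41 to 1.72, with exact permutation p = 0.8. In that list rps19, a ribosomal protein gene, had a log2 change of 0.37, matK of 0.20 and rbcL, the large Rubisco subunit, of 0.05 in line 348. The mean of the plastid list lay at -0.23 log2 units from the average of all arrays on control replicate 3, and without that array the direction of the list turned, with camera adjusted p = 0.984, and it was 0.217 without line 348 replicate 1 and 0.72 without line 348 replicate 2. For these plastid-encoded genes, line 348 against control, it was 0.227 with quantile normalization, 0.0926 with no filter on dim probe sets and 0.0772 without the intensity trend. In line 409 the plastid list had 39 of 69 probe sets higher, a median of 0.05 and a mean of -0.01, with camera adjusted p = 0.758, and 2 members passed over the list alone.

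Loci in fixed windows around the centromeres, where silenced repeats are dense, did not pass as a group with camera in either line. In line 409, 123 of 262 were higher, with a median log2 change of -0.01 and camera adjusted p = 0.967, and in line 348, 130 were higher, with camera adjusted p = 0.95. Annotated pseudogenes, a class that can include remnants of transposons, had 8 of 23 members higher in each line, with camera adjusted p = 0.654 in line 348 and 0.554 in line 409. The fry mixed test asks for changes in either direction. In line 409 its unadjusted p was 0.000156 for pericentromeric loci, 3.14e-05 for pseudogenes and 3.11e-05 for the 8 pericentromeric pseudogenes. In line 348 its unadjusted p was 0.187, 0.522 and 0.78. It sets members against no change and not against other probe sets, so it does not show that these loci differ from the rest. Without the filter on dim signal, 90 of 989 pseudogene probe sets had an unadjusted p under 0.05 in line 409, 68 of them higher, and 47 in line 348, 30 of them higher, where chance gives 49.45, and 1 was called in each line. In line 409 these were 9.1% of pseudogene probe sets, against 10.1% of all 22746 probe sets, and the higher ones were 6.88% against 5.26%. Dim signals went the same way outside pseudogenes: of the 7581 other probe sets that the filter leaves out, 548 had an unadjusted p under 0.05 in line 409, 400 of them higher. This comparison was added after the counts had been seen, and the difference between the shares was not tested. The 8 pericentromeric pseudogenes had a mean log2 change of -0.27 between line 409 and line 348, with camera adjusted p = 0.138. Members of that list that passed in line 409 over the list alone numbered 4, and over all probe sets none did. Of these AT5G32430, AT4G05510 and AT5G34920 were lower than in the control. AT4G08220 was higher, at 82.3 against 50.6 signal units, a log2 change of 0.615 with limma adjusted p = 0.245 over all probe sets. For AT5G32430, line 409 against control, the limma adjusted p was 0.0532 over all probe sets, but its signals in line 409, 7.04, 6.19 and 11.6, lay below the 40th percentile of each array, and its log2 change moved between -0.852 and -2.002 with the pseudocount.

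The number of pseudogene probe sets above the array's 40th percentile of signal, out of 989, was 21.7 ± 3.79 in the control, 18.0 ± 2.00 in line 348 and 19.7 ± 1.15 in line 409 (SD, n = 3). A 2-sided exact permutation test against the control gave p = 0.3 for line 348 and p = 0.7 for line 409, where 0.1 is the smallest p that 3 against 3 arrays allow. The S-adenosylmethionine cycle list had camera adjusted p = 0.554 in both lines and the photosynthesis list 0.781 and 0.554. In total 1 of 78 combinations of 26 lists and 3 contrasts passed with camera, 10 had an unadjusted p under 0.05, and with an estimated correlation 0 passed and 5 had an unadjusted p under 0.05.

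DDM1, MET1, CMT3, SAHH1 and ROS1, which maintain, write or remove DNA methylation or supply its methyl cycle, were to be reported in every array. The gene table used here assigns no probe set to any of these 5 genes, so they were not analysed here. Of 278 entries of the 17 fixed lists, 36 had a named probe set and 21 were tested, and the lists for DNA damage, heat shock, iron deficiency and seed storage had no tested member.

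Families of genes that share a symbol were also tested as lists, and none passed with camera. The lowest camera adjusted p, 0.0865, was that of family RPS in line 348, which holds members of the plastid list such as rps19. With an estimated correlation of 0.684 its camera p was 0.236. The autophagy genes of symbol ATG were ATG3 and members of the ATG8 group, 8 probe sets of which 7 were higher in each line. They had median log2 changes of 0.15 in line 348 and 0.16 in line 409, with camera adjusted p = 0.124 in both. Among them ATG8E had a log2 change of 0.37 in line 348 and ATG8F of 0.39 in line 409, and no member passed over the list alone in either line. The PRA1 family of small membrane proteins had 7 of 10 probe sets higher in line 348 and 9 of 10 in line 409, with camera adjusted p = 0.124 in both. Over the list alone, 3 of 8 members of family GSTU passed in line 348, with camera adjusted p = 0.554 for the family. By the same measure 1 member each of families PRA and UGT passed in line 348, and 1 each of TBL and UBP in line 409.

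Recovery of known changes was measured on simulated data, in which arrays and probe sets were drawn independently. With 20 changed probe sets per run, limma recovered 51% of 2-fold changes in line 348 and 46% in line 409, and 93% and 91% of 4-fold changes. With 200 changed per run it recovered 75.6% and 74.4% of 2-fold changes. Changes of 1.41-fold were recovered at 6% and 2% with 20 changed per run, so small shifts of single genes were mostly out of reach. The simulated data hold no structure between arrays, so recovery on the real arrays may be lower. Whether recovery differs between the lines was not tested.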

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

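The tests of array scaling (both of them), of dim signal and of a sequence difference were chosen after the result was seen, and the test of the chromosome region was written before it was run.

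AT5G22850 and probe set 266680_s_at stood out because their changes from the control differed between the 2 mutant lines in a direct test. The difference, line 409 minus line 348, was -1.537 log2 units for AT5G22850 and -1.751 for 266680_s_at. The latter has no gene in the table used here.

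For AT5G22850, line 409 against control, the log2 change was -1.704 with quantile normalization and -1.691 with median centring, which argued against a scaling error, while the median change of all tested probe sets, -0.0116, decided nothing because each array was scaled to the same trimmed mean. Noise of dim signal predicted a lost call with no pseudocount or with a higher one, but the limma adjusted p stayed at 0.00111 or lower. The call thus did not depend on the pseudocount. This test rescales the same signals, so it cannot tell whether those of line 409 were above background. The size of the change did depend on the pseudocount, at -1.881 with none and -1.266 with the higher one. On line 409 replicate 2 the signal, 17.5, lay below the 40th percentile of the array, 21.87. The 10 nearest named loci had a median log2 change of -0.0589, between -0.232 for CaS and 0.128 for AT5G22730, which argued against a change of the surrounding region. A sequence difference under the probes could not be tested, since 1 probe set was named for the gene and values per probe were not used here. A lower transcript level of AT5G22850 in line 409 is therefore possible, and so is a changed sequence; the labels name no insertion site that would tell them apart.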

How the results depend on the processing

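Called probe sets kept their direction under each alternative that tested them, and the plastid-encoded list in line 348 did not. The 6 unnamed ones were not tested with only probe sets with 1 gene, nor 258618_at with the stricter filter. AT5G22850 in both of its comparisons and 266680_s_at in line 348 were called wherever tested, 3 of 12 called results, with limma adjusted p up to 0.0162, 0.0418 and 0.0445. Of 133 single results, 13 not called were called under at least 1 alternative. The cause of the moved counts was not tested, except for the rise without control replicate 3, whose tests are reported as an observation of its own. Signal over background limited dim probe sets, and the filter kept those dim in 1 group, such as AT5G32430 in line 409.

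Calls in line 348 numbered 0 with only probe sets with 1 gene (401 with an unadjusted limma p under 0.05), 1 without trend, 10 with array weights, 6 with only the 6 arrays compared, and 24 with quantile normalization and no control replicate 3. In line 409 they numbered 40 with array weights and 53 with quantile normalization and no control replicate 3. Between the lines they numbered 1 with no filter, 1 with only probe sets with 1 gene and 1 without trend. Shared calls in limma numbered 0 with only probe sets with 1 gene (160 unadjusted), 0 without trend (330 unadjusted), 4 with array weights, 2 with only the 6 arrays compared, 0 at 2-fold (319 unadjusted) and 22 with quantile normalization and no control replicate 3. The alternative that joins quantile normalization and no control replicate 3 was chosen after seeing the data.

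List tests past the threshold with camera numbered 0 with quantile normalization (11 unadjusted), 0 with no filter (13 unadjusted), 4 with the stricter filter, 0 without trend (10 unadjusted), 2 with array weights, 0 with an estimated correlation (5 unadjusted), and 0 with quantile normalization and no control replicate 3 (8 unadjusted). With fry in place of camera they numbered 0 (13 unadjusted), and 9 with fry mixed. For the plastid-encoded genes, line 348 against control, the adjusted p was 0.227 with quantile normalization, 0.0926 with no filter, 0.0772 without trend, 0.916 with an estimated correlation and 0.797 with fry. Its direction turned without control replicate 3, at 0.984, and with quantile normalization and no control replicate 3, at 0.692.

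With each array left out in turn, calls ranged from 1 to 24 in line 348, 1 to 60 in line 409, 1 to 6 between the lines and 0 to 22 shared (202 to 308 unadjusted in limma where none was shared). List tests past the threshold with camera ranged from 0 (6 to 8 unadjusted) to 5, and the adjusted p of the plastid-encoded genes in line 348 from 6.16e-10 to 0.984.

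With the title number as a replicate block, calls numbered 1 in line 348 and 8 in line 409, shared calls in limma 0 (322 unadjusted) and list tests with camera 0 (8 unadjusted), with an adjusted p of 0.626 for the plastid-encoded genes in line 348. Deviations of arrays with the same number correlated at -0.116 to 0.192, with a median of -0.000862, and 2 of 9 pairs were over 0.1. Those with different numbers correlated at -0.177 to 0.124, with a median of -0.00263, and 1 of 18 pairs was over 0.1. No clear pairing by number was seen, but 2 arrays of line 348 share a number in their titles, so pairing was not excluded.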

Other observations

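The tests of groupings of the arrays, of the scaling of control replicate 3 and of the low-oxygen response were written before they were run, while those of RNA degradation, of a mutant array, of pooled trios and of shared control noise were chosen after results were seen.

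Genes known to rise under low oxygen were counted among the probe sets called without control replicate 3, with a list written from memory after those calls had been seen. AT2G17850 had signals of 24.5, 30.2 and 103 on the 3 control arrays, CML38, a calmodulin-like gene, had 46.4, 35.2 and 126, and AT4G10270 had 240, 227 and 575. PDC2, a pyruvate decarboxylase of fermentation, had 40.8, 39.9 and 73.5. Of the 20 named probe sets called higher in either line without that array, 15 were in the list, against 0.407% of the 7614 named probe sets, but the list was chosen for these calls and is not independent evidence.

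With all 9 arrays, 25 of the 31 list members were higher in line 348, with a mean log2 change of 0.41, and 28 were higher in line 409, with a mean of 0.64. The camera p at the preset correlation was 1.01e-10 and 3.01e-16. With an estimated correlation the camera p was 0.085 and 0.0403, adjusted p = 0.127 and 0.121 over the 3 contrasts of this list alone. Of the 31 members, 15 were among the calls seen before the list was written. These p-values come from largely the same arrays and are therefore no independent test of the list. Without control replicate 3 the median log2 change went from 0.47 to 0.72 in line 348 and from 0.61 to 0.94 in line 409, with estimated-correlation p of 0.00653 and 0.00528, for a list chosen after those calls were seen. The list mean per array, in log2 units from the average, was -0.65, -0.57 and 0.17 in the control, 0.24, -0.15 and 0.10 in line 348 and 0.16, 0.42 and 0.28 in line 409.

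Leaving out control replicate 3 raised the calls of line 409 from 6 to 60, and several explanations were weighed. Array scaling was argued against by 53 calls after quantile normalization without that array, while RNA degradation stayed open, since the 3'/5' ratio on control replicate 3 lay inside the range of the other 8 arrays for 2 of 3 genes but was the highest of all, 1.97, for GAPDH. If control replicate 3 were a mutant array it would lie nearer to the line mean on most called probe sets, and it did on 78.6%, but these probe sets were picked for the pattern, and control replicates 1 and 2 deviating together predicts the same. A second test, chosen after that value was seen, asked whether control replicate 3 could be an array of line 348 or line 409, and 0 of 2 lines held it in range on both AT5G22850 and 266680_s_at, although line 409 held it on 266680_s_at, so that for line 409 the result rests on AT5G22850 alone. A low-oxygen response that differs between arrays stayed open: against control replicates 1 and 2, the 16 list members not called had means of 0.334 on control replicate 3, 0.209 in line 348 and 0.355 in line 409, so the 2 low control arrays account for the value as well.

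The log2 changes of the 2 lines against the control were correlated, but a common shift of the lines was not established. Their covariance, 0.0288, was matched or passed in 15 of 100 groupings of the 9 arrays, the highest other being 0.035. A similar covariance could thus arise without regard to the lines. Noise of the shared control arrays alone predicted a value inside the simulated range, which ended at 0.021, and that prediction was not met, but the simulation holds no structure between arrays, so this was left undecided. With the 6 mutant arrays pooled against the control, 4 of 84 trios gave at least the real 6 calls, and the highest other gave 20. Trios of control replicates 1 and 2 with 1 mutant array gave 1, 20 and 7 calls for line 348 and 11, 0 and 0 for line 409; a trio above the real count points to a structure of the samples, though a difference of the lines gives calls in such trios too, and no test told these apart.

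Splits of the 6 arrays of a comparison numbered 10, too few for a share under 0.05. In line 348, 2 splits gave at least the real 3 calls, the highest other 3, in line 409, 2 gave at least the real 6, the highest other 9, and between the lines 1 gave the real 2, the highest other 0. Groupings with at least the 1 shared call numbered 5 of 100, the highest other with 1, and those with at least the 1 list test past the threshold numbered 79 of 100, the highest other with 8.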
